A study of Mus musculus with 13 samples.

How the data were processed

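MicroRNA levels were measured on 13 mouse samples with 1-colour Agilent arrays (Cy3). The 12 arrays of primary cells fall into 4 groups of 3 biological replicates. DN are CD4-negative CD8-negative thymocytes and DP are CD4-positive CD8-positive thymocytes, both sorted from the thymus of C57BL/6 mice. ES and LS are early-stage and late-stage T-cell acute lymphoblastic leukaemia (T-ALL), sorted as CD4-positive CD8-positive cells from the spleen of bone marrow chimeras whose marrow carried N1ICD, the active intracellular part of Notch1. M295, a cultured mouse T-ALL line, has 1 array. RNA was prepared with the miRNeasy kit. The T-ALL cells thus come from spleen and the thymocytes from thymus, so tissue and disease cannot be told apart in any comparison between them.

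Each array held 49324 spots, of which 47160 were not controls. These represent 1122 mouse miRNAs and 57 viral miRNAs by 2982 probes, with 1 to 4 probes per mouse miRNA, under the names of miRBase release 18. Genome coordinates are not given here, since the measured features are mature miRNAs known by their array names.

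Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1, and every spot has a fluorescence intensity. The deposited scanner files hold the background-subtracted intensity of each spot, the raw median pixel intensity of spot and local background, and a total intensity per miRNA. None of these is scaled between arrays. The value table deposited by the authors is on the log2 scale and quantile normalized. This was established by comparison with the scanner files: its columns rank the miRNAs as the total intensity of the same array does, and all columns have a median of 3.29. The authors' processing notes name RMA, affy, MAS5 and GCOS without versions or roles. No spot was saturated.

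Values were computed from the background-subtracted intensity after control spots and outlier spots were removed (4.03 to 8.60% of spots per array). Spots were averaged per probe and probes per miRNA on the linear scale. Each array was divided by its 75th percentile over the 108 mouse miRNAs well above background on all 12 primary arrays. A common floor was set at -7.59 on the log2 scale, the median over the 12 arrays of the lowest scaled signal among miRNAs well above background, and values were then put on the log2 scale. A miRNA counts as above background on an array when at least 50% of the kept spots of at least 1 of its probes carry the software's mark for a signal well above background. The 229 mouse miRNAs above background on all 3 arrays of at least 1 group were tested.

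The 12 primary arrays were fitted together in limma 3.58.1 under R 4.3.3 (files were read with the R package data.table, version 1.17.8), with 1 mean per group, lmFit and eBayes without an intensity trend. A miRNA was called when its Benjamini-Hochberg adjusted p within a comparison was under 0.05. The comparisons were T-ALL (ES and LS, each with equal weight) against thymocytes (DN and DP, each with equal weight), ES against DP, LS against DP, LS against ES, DN against DP, ES against DN and LS against DN. Errors beside fold changes are standard errors of the fit, and those beside group means are standard deviations. Where the lower group was above background on none of its arrays, the fold is a lower bound, computed with each of its arrays set to the higher of its value and the lowest signal above background on that array, and is written as at least N-fold. The number of miRNAs above background per array was compared by an exact permutation test. The M295 array was left out of the fit because 1 array gives no spread, and its values are compared with the range of the 6 T-ALL arrays without a test.

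Lists of miRNAs were fixed before the data were examined, as were the groups, the naming rule and all settings tried other than the 4 named as added. The tests were too, except those of the results flagged for a closer look. The 12 lists with at least 3 tested members were the let-7 family, lymphocyte activation miRNAs, the miR-148, miR-152 and miR-26 families, the miR-15/16 family, the miR-17~miR-92 cluster and its paralogs, the miR-181 family, the miR-232724 clusters, the miR-29 family, the miR-30 family, miRNAs known as oncogenic in T-ALL, miRNAs known as tumour-suppressive in T-ALL, and the Sfmbt2 cluster. The last is named after a large imprinted group of miRNA genes in an intron of Sfmbt2. It holds every mouse array name that starts with miR-297, miR-466, miR-467 or miR-669. The locus of each member was not checked, so some may lie elsewhere. Lists with fewer tested members were miR-21, the miR-34 family, the clusters of miR-99 or miR-100 with let-7 and miR-125, the Dlk1-Dio3 imprinted cluster, and markers of erythroid, myeloid, mature lymphocyte, endothelial and stromal, and epithelial cells and of liver, muscle and brain. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Unless fry is named, a list call is that of camera at the preset correlation.

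miRNAs were named by a rule: among calls whose groups do not overlap and whose higher group is above background on all arrays, those with the largest rises and falls (10 each for T-ALL against thymocytes, 8 each for DN against DP and for LS against ES, 6 each for ES and for LS against DP). To these come miR-21-5p and up to 4 members per list with the largest absolute fold change in each comparison, and the 8 miRNAs furthest above and below the T-ALL range for M295.

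The 13 arrays sit on 2 slides, 7 on slide 1 and 6 on slide 2, each scanned in 1 session, and each slide holds arrays of all 4 primary groups. Slide 1 holds DN 1, DP 1, ES 1, ES 2, LS 1, LS 2 and M295, and slide 2 holds the other 6. Within a slide some groups have 1 array, which is assumed to vary like the others. The labels do not say that a replicate number marks a shared animal or day. After group means were removed, the 3 DP and LS pairs with the same number each correlated over 0.1 (0.18 to 0.50), and in no other pair of groups did all 3, with 6 of the 18 same-number pairs over 0.1 in all. However, DP 1 correlated more with LS 2 (0.25) than with LS 1 (0.22), and DP 2 more with LS 1 (0.26) than with LS 2 (0.18). The numbers are thus not shown to pair DP and LS either. Slide was used as a block and as a restriction, the replicate number as a block. Further alternatives were another 75th percentile (over all 1122 mouse miRNAs), quantile normalization, normexp background with an offset of 50, an RMA-like route, the deposited value table, the software's total signal, other summaries of probes, a floor halved or doubled, no filter or a filter for signal on all arrays, an added log2 fold change of at least 1, array weights, a robust trend in eBayes, only the groups compared in the fit, and leaving out each of the 12 arrays. The scanner files hold no mean pixel intensity, so the normexp and RMA-like alternatives used the median pixel intensity. The offset draws the fold changes of dim miRNAs towards 0 by construction. After the data were seen, 4 alternatives were added: tests restricted to array names that match a miRNA gene of the mouse reference gene table, list tests without ES 1 or without ES 3, the replicate number as a block for DP and LS alone, and the comparison of M295 over miRNAs above background on all 7 arrays.

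The chain was tested on simulated data with 60 changed miRNAs among 229, in 20 runs. For T-ALL against thymocytes, 75.0% of simulated log2 changes of 1 and 93.2% of changes of 2 were recovered, with 3.93% false calls. For LS against ES, 50.0% and 86.0% were recovered, with 4.37% false calls. The simulated noise was independent, with the same spread of a miRNA in every group, which the real groups need not have. The 3.93% and 4.37% therefore do not give the share of false calls in the real comparisons. A shifted list was found in 100% of the runs and an unshifted list was called in 5% of them. The simulated lists were random sets of 8 miRNAs with independent noise, which members of a cluster or family need not have. The 5% therefore does not give the share of false calls for the real lists. Arrays give no count that sets a detection limit, so the precision rests on the number of arrays.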

Results

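MicroRNAs were profiled in DN thymocytes, DP thymocytes, early-stage T-ALL (ES) and late-stage T-ALL (LS), with 3 arrays per group, and in the T-ALL line M295 with 1 array. The question the groups address is which miRNAs differ between Notch1-driven leukaemic T cells and the normal thymocytes they resemble, and whether they differ between stages of the disease. The number of mouse miRNAs above background was 180 ± 19.7 in DN, 211 ± 13.1 in DP, 185 ± 65.2 in ES and 217 ± 10.1 in LS (mean ± SD, n = 3 arrays each). Single arrays ranged from 115 on ES 1 to 244 on ES 3, and M295 had 257. The 6 T-ALL arrays exceeded the 6 thymocyte arrays by 5.67 miRNAs on average, less than the spread between replicates (exact permutation test, two-sided, p = 0.803). ES 1 also had the noisiest background, with a standard deviation of its negative controls of 18.7 against at most 7.11 on every other array.

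**Figure D1:**
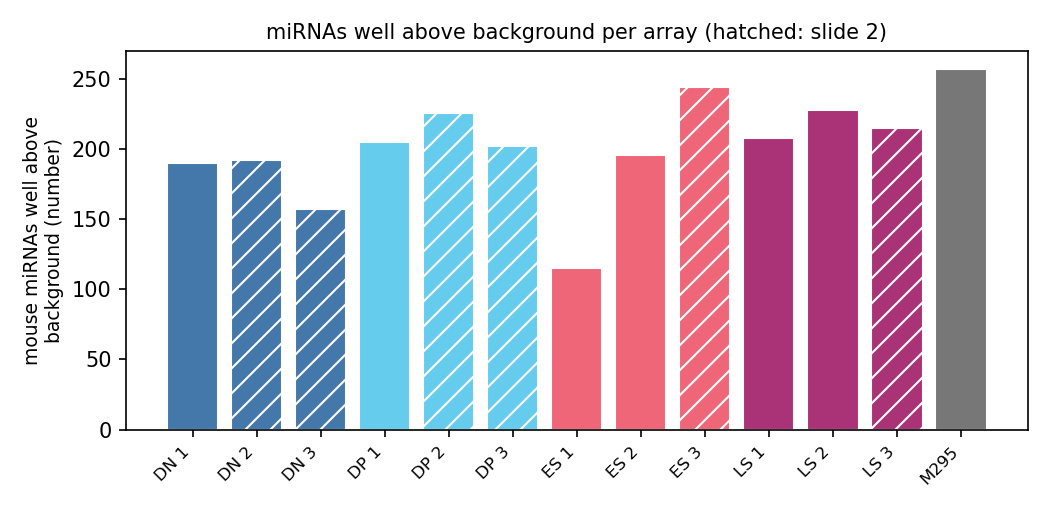
Bars give the number of mouse miRNAs well above background on each of the 13 arrays, with hatching for arrays on slide 2. ES 1 has 115 and every other primary array has between 157 and 244.

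The comparison of T-ALL with thymocytes asks which miRNAs differ in the leukaemia as a whole. miR-21-5p, known as oncogenic in many cancers, was 4.40-fold higher in T-ALL, with a log2 signal of 2.26 ± 0.73 against 0.12 ± 1.27 (SD, n = 6 arrays each; log2 fold change 2.14, SE 0.29, adjusted p = 3.24e-04). miR-721 rose most among the miRNAs named by the rule, 9.37-fold (log2 fold change 3.23, SE 0.36, adjusted p = 1.50e-04), and was higher on every T-ALL array than on any thymocyte array. miR-449a-5p, which shares its seed with the tumour-suppressive miR-34 family, rose 5.51-fold (log2 fold change 2.46, SE 0.45), and miR-342-3p, a miRNA of lymphocytes, rose 3.97-fold (1.99, SE 0.26). miR-128-3p fell 3.09-fold (log2 fold change -1.63, SE 0.24, adjusted p = 5.60e-04) and miR-148a-3p fell 9.83-fold (-3.30, SE 0.73, adjusted p = 0.00392), with an SD of 2.02 among the T-ALL arrays and 2 of the 6 above background.

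In all, 131 of the 229 tested miRNAs differed between T-ALL and thymocytes, 72 higher and 59 lower. The other named rises were miR-714 (log2 fold change 2.96), miR-5128 (2.26), miR-211-3p (2.16), miR-5109 (2.10), miR-706 (1.80), miR-5105 (1.79) and miR-5126 (1.74). Of these, miR-714, miR-5109 and miR-5105 are array names that matched no miRNA gene in the mouse reference gene table. Of the 14 tested names without a match 9 rose, against 63 of the other 215. Among the 9 is miR-3102-5p.2-5p, which the form of its name left unmatched although miR-3102-5p matched a gene. The other named falls were miR-30a-5p (log2 fold change -1.18), miR-181c-5p (-1.17), miR-296-5p (-0.93), miR-374c-5p (-0.77), miR-181d-5p (-0.76), miR-25-3p (-0.62), miR-30e-3p (-0.60), miR-130b-3p (-0.47) and miR-301a-3p (-0.43). The call of miR-130b-3p ended without any 1 of 9 arrays (all but ES 1, ES 2 and ES 3), with adjusted p up to 0.0920, and its log2 fold change without ES 3 was -0.31. A block for slide left 118 miRNAs called. There were 30 within slide 1, where miR-21-5p was not called (log2 fold change 1.90, adjusted p = 0.102), and 150 within slide 2 (miR-21-5p 2.53, adjusted p = 0.00103).

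The miR-181 and miR-30 families were lower in T-ALL than in the average of DN and DP thymocytes. All 4 members of the miR-181 family, which tunes T-cell receptor sensitivity in developing thymocytes, fell: miR-181a-5p by 2.84-fold (log2 fold change -1.50, SE 0.38), miR-181b-5p by 1.77-fold (-0.82, SE 0.19), and miR-181c-5p and miR-181d-5p as above (4 also adjusted over the list alone). The list was called (camera adjusted p = 0.0413, adjusted p = 0.499 with an estimated correlation, and fry adjusted p = 9.15e-05). All 5 members of the miR-30 family fell, among them miR-30c-5p (log2 fold change -0.73, SE 0.12) and miR-30e-5p (-0.65, SE 0.13), and 5 also adjusted over the list alone (camera adjusted p = 0.0413, adjusted p = 0.842 with an estimated correlation, and fry adjusted p = 0.00352). The call of miR-30b-5p ended without any 1 of 10 arrays (all but ES 3 and LS 3; adjusted p up to 0.102) and with slide as a block (0.0941). Against DN alone less of this was seen: miR-181a-5p was at -0.98 in T-ALL, -0.83 in DN and 1.88 in DP. In LS against DN, 0 members of either family were called by limma, also adjusted over the list alone, and 1 of each had an unadjusted p under 0.05, with medians of -0.16 for miR-181 and -0.21 for miR-30 (camera adjusted p = 0.267 and 0.189, fry 0.351 for each). In ES against DN, 2 of 4 and 1 of 5 fell, miR-181c-5p, miR-181d-5p and miR-30a-5p. Of 27 tested members of the Sfmbt2 cluster, 12 fell and 4 rose (13 and 4 adjusted over the list alone), with a camera adjusted p = 0.0413, and adjusted p = 0.842 with an estimated correlation (fry adjusted p = 0.0713). The falls of the Sfmbt2 members are falls from DP: against DN 0 members fell by limma (1 in ES and 0 in LS at an unadjusted p under 0.05), while 1 rose in ES and 5 in LS (1 and 4 adjusted over the list alone), and miR-669n, for example (log2 fold change -1.57, SE 0.38), was at -4.73 in T-ALL, -4.38 in DN and -1.94 in DP. Without ES 1 the calls of these 3 lists ended, with adjusted p of 0.0687 for miR-181, 0.0706 for miR-30 and 0.150 for the Sfmbt2 cluster, and without ES 3 that of the Sfmbt2 cluster ended (0.147). All 3 were at 0.0561 with slide as a block.

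The other 9 lists were not called by camera in T-ALL against thymocytes, and fry called 3 of them as lower: miR-15/16 (adjusted p = 0.0121), the oncogenic list (0.0148) and the miR-148, miR-152 and miR-26 families (0.0358). The numbers of members that fell, and in brackets the number adjusted over the list alone, were 3 of 5 in the miR-15/16 family (3), 3 of 4 in the miR-148, miR-152 and miR-26 families (3), 1 of 8 in let-7 (0), 1 of 12 in the miR-17~miR-92 list (1), 1 of 5 oncogenic miRNAs (1) and 1 of 6 tumour-suppressive miRNAs (1). miR-26a-5p, a repressor of the histone methyltransferase Ezh2, fell 3.14-fold (log2 fold change -1.65, SE 0.40), and miR-15b-5p fell 1.33-fold (-0.42, SE 0.11). With slide as a block the calls of miR-16-5p (adjusted p = 0.0702), miR-26b-5p (0.0863) and let-7g-5p (0.0639), which these counts include, ended, and each also ended without any 1 of 7 to 9 arrays (adjusted p up to 0.0789, 0.0878 and 0.0730). Among 6 lymphocyte activation miRNAs, miR-21-5p rose and miR-155-5p, which is induced in activated lymphocytes, fell 6.13-fold (log2 fold change -2.62, SE 0.77, adjusted p = 0.0146), with 1 and 1 adjusted over the list alone. In the miR-29 family and the miR-232724 clusters 0 members were called by limma, also over the list alone, and 0 of 3 and 2 of 5 had an unadjusted p under 0.05. Camera adjusted p ranged from 0.130 (miR-15/16) to 0.958 (lymphocyte activation, miR-232724 and tumour-suppressive miRNAs). For the miR-232724 and tumour-suppressive lists the median log2 fold changes, 0.27 and 0.04, and the means, -0.17 and -0.37, differ in sign, and for lymphocyte activation camera points down and fry up. No camera call of a list in any comparison held with an estimated correlation.

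ES and LS were each set against DP thymocytes, which share their CD4-positive CD8-positive surface type. miR-21-5p was 11.7-fold higher in ES (log2 signal 2.52 ± 0.78 against -1.04 ± 0.20, SD, n = 3 each; log2 fold change 3.55, SE 0.42, adjusted p = 1.12e-04) and 8.19-fold higher in LS (2.00 ± 0.72; log2 fold change 3.03, SE 0.42, adjusted p = 2.33e-04), on every T-ALL array above every DP array. miR-342-3p was 5.48-fold higher in ES (log2 fold change 2.45, SE 0.37) and 5.28-fold higher in LS (2.40, SE 0.37). miR-181a-5p was 9.19-fold lower in ES (log2 fold change -3.20, SE 0.54, adjusted p = 9.84e-04) and 5.73-fold lower in LS (-2.52, SE 0.54, adjusted p = 0.00314). miR-148a-3p was 14.1-fold lower in LS (log2 fold change -3.82, SE 1.03, adjusted p = 0.0105), where 1 of 3 arrays had it above background.

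In ES, 106 miRNAs differed from DP, 48 higher and 58 lower, and in LS 134 did, 74 higher and 60 lower. Further named rises in ES were miR-721 (log2 fold change 2.95), miR-714 (2.94), miR-5128 (2.41) and miR-211-3p (2.18). The call of miR-211-3p ended without DP 3 (adjusted p = 0.0620), and that of miR-5128 without DP 1, DP 2, DP 3 or ES 3 (adjusted p up to 0.0925, log2 fold change 1.48 without ES 3). Further named rises in LS were miR-714 (4.55), miR-721 (3.78), miR-451 (4.31, SE 1.17), miR-3472 (at least 10.9-fold) and miR-1940 (at least 8.40-fold), and miR-714 and miR-1940 have no gene in the reference gene table. miR-451 is a miRNA of red blood cells, and its LS values ranged widely (SD 2.07, n = 3). The named falls in ES were miR-32-3p (at least 14.7-fold), miR-468-3p (log2 fold change -4.06), miR-672-5p (at least 9.99-fold), miR-466m-5p (at least 8.73-fold), miR-466h-5p (at least 8.0-fold) and miR-669n (-3.39). In LS they were miR-672-5p (-3.33), miR-32-3p (-3.15), miR-155-5p (-3.07), miR-466h-5p (-2.87) and miR-468-3p (-2.85), besides miR-148a-3p. The call of miR-155-5p in LS ended without DP 1, DP 2, DP 3, LS 2 or LS 3 (adjusted p up to 0.112), with slide as a block (0.0583) and with the replicate number as a block for DP and LS (0.0526).

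Against DP, all 4 members of the miR-181 family fell in ES (4 adjusted over the list alone) and 3 in LS (4 over the list alone), with camera adjusted p = 0.0156 in ES, and adjusted p = 0.294 with an estimated correlation, and 0.0410 in LS, and adjusted p = 0.648 with an estimated correlation. All 5 members of the miR-30 family fell in each stage, miR-30c-5p by 1.21 on the log2 scale in ES and 1.04 in LS (5 and 5 adjusted over the list alone). The calls of miR-30b-5p ended without DP 2, DP 3, ES 1 or ES 2 in ES and without any DP array or LS 1 in LS (adjusted p up to 0.0691 and 0.0968), and that of miR-30a-5p in LS without any 1 of 8 arrays (up to 0.104). The call of miR-30a-5p in LS also ended with the replicate number as a block for DP and LS. The family's camera adjusted p was 0.0214 in ES, and adjusted p = 0.680 with an estimated correlation, and 0.0369 in LS, and adjusted p = 0.882 with an estimated correlation. Of the miR-15/16 family, which restrains the cell cycle, 4 of 5 fell in ES and 5 of 5 in LS (4 and 5 adjusted over the list alone), with miR-15b-5p at -0.87 and -0.90. Its camera adjusted p was 0.0495 in ES, and adjusted p = 0.680 with an estimated correlation, and 0.0369 in LS, and adjusted p = 0.882 with an estimated correlation. Of the 27 Sfmbt2 cluster members, 13 fell and 1 rose in ES and 11 fell and 1 rose in LS, with the same numbers adjusted over the list alone. Its camera adjusted p was 5.07e-04 in ES, and adjusted p = 0.680 with an estimated correlation, and 0.0369 in LS, and adjusted p = 0.882 with an estimated correlation. The calls of miR-15/16 in ES without ES 1 (adjusted p = 0.0650) and of the Sfmbt2 cluster in LS without ES 3 (0.0528) ended, and with slide as a block miR-15/16 in ES was at 0.0617. When arrays were scaled over all mouse miRNAs, the calls of miR-15/16 and miR-30 ended in ES (both 0.189), and those of miR-15/16, miR-30 and miR-181 ended in LS (each 0.0637). With the replicate number as a block for DP and LS the same 3 calls in LS ended (0.0501, 0.0501 and 0.0603). Fry called the miR-181, miR-30, miR-15/16 and Sfmbt2 lists as lower in both stages. Its adjusted p ranged from 1.77e-05 (miR-181 in ES) to 0.0373 (Sfmbt2 in LS).

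The other 8 lists were not called by camera in either stage, and fry called the miR-148, miR-152 and miR-26 families as lower in LS (adjusted p = 0.0373). miR-26a-5p fell by 2.60 in ES and by 2.09 in LS on the log2 scale, among 2 and 3 members that fell of the miR-148, miR-152 and miR-26 families (2 and 3 adjusted over the list alone). Of the let-7 family 1 fell in ES and 3 in LS (0 and 2 adjusted over the list alone), and its median in ES, -0.34, was 0.20 when arrays were scaled over all mouse miRNAs. Of the 12 miR-17~miR-92 members, 1 fell in each stage, miR-25-3p (log2 fold change -0.79 in ES and -0.76 in LS; 1 and 0 adjusted over the list alone). The median and mean differ in sign in LS for the miR-232724 clusters (0.59 and -0.09), lymphocyte activation (-0.47 and 0.14), oncogenic (0.30 and -0.24) and tumour-suppressive miRNAs (0.09 and -0.23). For the oncogenic list in ES and the miR-17~miR-92 list in LS camera points down, while median and mean are above 0 (0.25 and 0.26, and 0.03 and 0.11). Fits with slide as a block called 97 miRNAs in ES and 127 in LS, fits within slide 1 called 29 and 56, and fits within slide 2 called 165 and 148. Without DP 3 the ES count was 69. Within slide 1 miR-21-5p was at 3.01 in ES (adjusted p = 0.114) and 3.03 in LS (0.0839), and within slide 2 at 4.50 (6.58e-04) and 2.90 (0.00222).

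The ES and LS lists overlapped in 94 miRNAs, 47 higher in both and 47 lower in both, and none moved in opposite directions. Independent lists of these sizes would share 15.5 and 15.2. Both comparisons use the same 3 DP arrays, and 100 simulations of unchanged groups with shared DP arrays gave 0 shared calls, a value that an adjusted threshold nearly fixes where nothing changes. Across the tested miRNAs, which are not independent replicates, the fold changes correlated at 0.906, against 0.522 in the simulations. Their covariance was 2.11, against 0.138 in the simulations. The 3 DP arrays cannot be divided between the comparisons, so part of the excess may come from them.

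**Figure D2:**
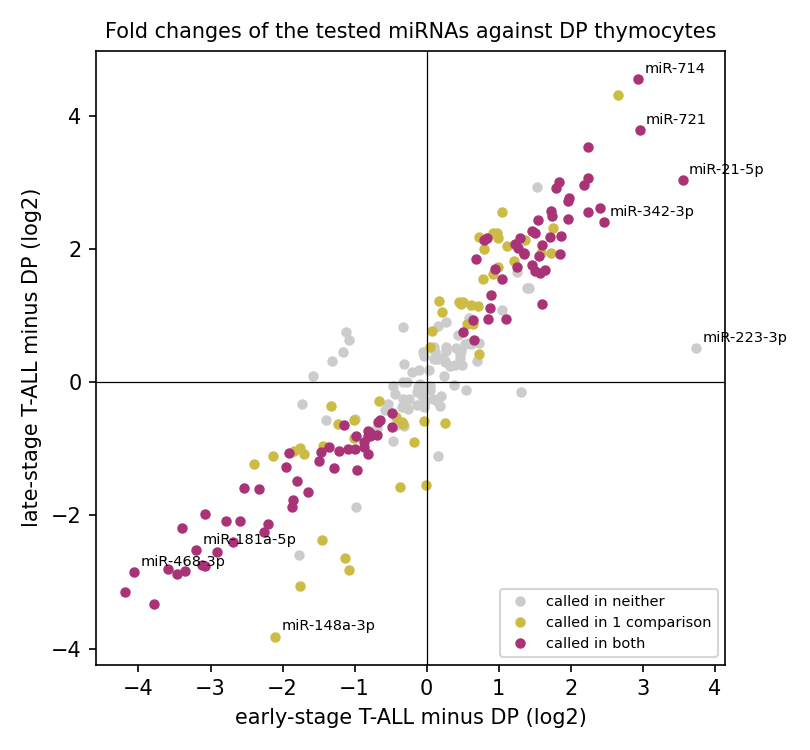
Each point is 1 of the 229 tested miRNAs, with the log2 fold change of early-stage T-ALL over DP on the horizontal axis and of late-stage T-ALL over DP on the vertical axis. The 94 miRNAs called in both lie at the upper right and at the lower left, with miR-21-5p at 3.55 and 3.03 and miR-181a-5p at -3.20 and -2.52.

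Late-stage and early-stage T-ALL were compared directly to ask what changes as the disease advances. In LS, miR-712-5p was 2.73-fold higher (log2 fold change 1.45, SE 0.32, adjusted p = 0.0388), miR-3473b 2.51-fold (1.33, SE 0.22, adjusted p = 0.0202), miR-344i 2.50-fold (1.32, SE 0.23, adjusted p = 0.0202), miR-3473 2.24-fold (1.16, SE 0.22, adjusted p = 0.0238) and miR-690 1.95-fold (0.96, SE 0.21, adjusted p = 0.0388). miR-3968 was 1.82-fold lower (log2 fold change -0.86, SE 0.18, adjusted p = 0.0388). The 3 arrays of each stage did not overlap for any of these 6, which chance gives to 10% of miRNAs, and miR-712-5p has no gene in the reference gene table. miR-21-5p differed by -0.52 (95% interval -1.44 to 0.40, adjusted p = 0.508) and miR-451 by 1.65 (95% interval -0.94 to 4.24, adjusted p = 0.463), both within the spread between leukaemias.

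No other miRNA was called between the stages, and 34 had an unadjusted p under 0.05 in limma. Camera called the lymphocyte activation list, the miR-29 family, which represses DNA methyltransferases, and the tumour-suppressive list as lower in LS, each at adjusted p = 0.0403, and adjusted p = 0.542 with an estimated correlation, with 0 members called by limma, also adjusted over the list alone, and 0 with an unadjusted p under 0.05 (fry adjusted p = 0.852 for each). Without ES 3, whose miR-29a-3p, miR-29b-3p, miR-223-3p and miR-146a-5p stood above the other leukaemias, these 3 adjusted p were 0.505, 0.485 and 0.489, and the number of miRNAs called was 55. With slide as a block 3 miRNAs were called. Within slide 1 limma called 0, with 56 at an unadjusted p under 0.05, and within slide 2, where ES 3 and LS 3 are alone in their groups, it called 114. The calls rest on single arrays: limma called 1 miRNA without LS 1, 2 without each of the 3 DN arrays, and 3 without each of the 3 DP arrays, ES 1, ES 2 or LS 2.

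DN and DP are successive stages of normal thymocyte development. DN cells had 49.4-fold more miR-451 (log2 signal -0.26 ± 0.22 against -5.89 ± 0.50, SD, n = 3 each; log2 fold change 5.63, SE 1.17, adjusted p = 0.00466) and at least 8.63-fold more miR-144-3p, both miRNAs of the red cell lineage. miR-126-3p, a miRNA of endothelium and of blood stem and progenitor cells, was at least 3.84-fold higher in DN (adjusted p = 0.00559), and miR-21-5p was 4.96-fold higher (log2 fold change 2.31, SE 0.42, adjusted p = 0.00225). Like miR-451, miR-144-3p and miR-126-3p, the myeloid marker miR-223-3p was above background on all 3 DN arrays. Whether the DN sort held cells of other types was not tested. DP cells had 6.54-fold more miR-181a-5p (log2 fold change DN minus DP -2.71, SE 0.54, adjusted p = 0.00393). They also had at least 13.2-fold more miR-672-5p, and at least 10.6-fold more miR-32-3p.

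In all, 67 miRNAs differed between DN and DP, 24 higher and 43 lower in DN. Other named rises in DN were miR-101a-3p (at least 6.08-fold), miR-494-3p (log2 fold change 2.20), miR-101b-3p (2.04) and miR-18a-5p (1.69), a member of the growth-promoting miR-17~miR-92 cluster. Other named falls were miR-466m-5p (at least 9.56-fold), miR-468-3p (log2 fold change -3.20), miR-669e-5p (at least 8.43-fold), miR-669k-5p (at least 7.74-fold), miR-466j (at least 7.50-fold) and miR-466h-5p (-3.06). Of the 27 Sfmbt2 cluster members 12 fell in DN and 0 rose (12 and 0 adjusted over the list alone), with a camera adjusted p = 3.99e-05, and adjusted p = 0.634 with an estimated correlation. With normexp background 6 members fell and the median log2 fold change of the list was 0.04, with RMA-like processing these were 11 and -0.17, and with the other 3 scalings 12 fell, with medians between -0.93 and -0.77. The cluster gave 5 of the 15 mouse features that were above background on every DP array and on no other primary array, and all 15 were above background on M295. Of the miR-15/16 family 4 of 5 fell in DN (4 adjusted over the list alone), with miR-15a-5p at -0.98 (SE 0.17) and miR-16-5p at -0.92 (SE 0.17), camera adjusted p = 0.0471, and adjusted p = 0.634 with an estimated correlation. That call ended when arrays were scaled over all mouse miRNAs (adjusted p = 0.124). In the other lists, 3 of 4 miR-181 members and 3 of 5 miR-30 members fell (3 and 4 adjusted over the list alone) and 2 of 12 miR-17~miR-92 members rose (2), with camera adjusted p of 0.0738, 0.0882 and 0.0512. The calls of miR-30d-5p and miR-19a-3p among these ended without any 1 of the DN and DP arrays (adjusted p up to 0.135) and without any 1 of these but DP 2 (up to 0.0887). Fry called miR-181 (adjusted p = 9.14e-04), miR-15/16 (0.00411), the Sfmbt2 cluster (0.00677) and miR-30 (0.0163) as lower and the oncogenic list as higher (0.0131).

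With slide as a block 67 miRNAs were called, against 18 within slide 1, where DN and DP have 1 array each, and 123 within slide 2. Leaving out DP 3 gave 44 calls and leaving out ES 3 gave 101, the call of miR-18a-5p ended without DP 3 (adjusted p = 0.0590), and that of miR-144-3p ended without any 1 of the DN and DP arrays (adjusted p up to 0.107).

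ES and LS were also compared with DN, the less mature thymocytes. miR-449a-5p was 11.4-fold higher in ES (log2 fold change 3.51, SE 0.64, adjusted p = 0.0132) and 11.6-fold higher in LS (3.53, SE 0.64, adjusted p = 0.00420), and miR-342-3p was 2.99-fold higher in ES (1.58, SE 0.37) and 2.88-fold in LS (1.53, SE 0.37). miR-126-3p was at least 4.15-fold lower in ES and at least 4.90-fold lower in LS. miR-148a-3p was 22.5-fold lower in LS (log2 fold change -4.49, SE 1.03, adjusted p = 0.0120). miR-21-5p differed from DN by 1.24 in ES (95% interval 0.32 to 2.16, adjusted p = 0.111) and by 0.72 in LS (95% interval -0.20 to 1.65, adjusted p = 0.228), so neither difference passed the correction.

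ES differed from DN in 15 miRNAs, 9 higher and 6 lower, and LS in 76, 59 higher and 17 lower. The miR-17~miR-92 list was called as lower than in DN in both, with 0 of 12 members called by limma, also adjusted over the list alone, and 2 in ES and 1 in LS at an unadjusted p under 0.05. Its adjusted p was 0.0298 in ES, and adjusted p = 0.939 with an estimated correlation, and 0.0109 in LS, and adjusted p = 0.630 with an estimated correlation. Its call in ES ended without ES 3 (adjusted p = 0.802), and fry called it in neither (adjusted p = 0.414 and 0.351). The oncogenic list was called as lower by fry (0.00598 in ES and 0.00451 in LS) and not by camera (0.281 and 0.187), with 0 of 5 members called by limma and 0 at an unadjusted p under 0.05. The miR-181 family was called in ES by camera (adjusted p = 0.0429, and adjusted p = 0.468 with an estimated correlation) and by fry (0.00598). There 2 of 4 members fell, miR-181c-5p and miR-181d-5p (2 adjusted over the list alone). The camera call ended without ES 1 (adjusted p = 0.148). Of the miR-30 family miR-30a-5p fell in ES (log2 fold change -1.39, SE 0.36; 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.144, fry 0.192). The calls of these 3 miRNAs ended with slide as a block (0.0531, 0.0769 and 0.0875), and without any 1 of the DN and DP arrays (miR-181c-5p, adjusted p up to 0.127), of these and the LS arrays (miR-181d-5p, up to 0.182) or of all but ES 3 (miR-30a-5p, up to 0.175). With slide as a block 9 miRNAs were called in ES and 73 in LS, against 3 and 3 within slide 1 and 137 and 118 within slide 2. Without DN 1, DN 2 or DN 3 limma called 0 miRNAs in ES (38, 45 and 36 at an unadjusted p under 0.05), with adjusted p of miR-449a-5p and miR-126-3p up to 0.0691 and of miR-342-3p up to 0.146. Without DP 1, DP 2 and DP 3 the ES counts were 5, 5 and 6, and they were 40 without ES 2 and 23 without ES 3. For LS the counts without DN 1, DN 2 and DN 3 were 40, 43 and 41. Leaving out LS 1 gave 32 and ended the call of miR-342-3p (adjusted p = 0.0541), and leaving out ES 3 gave 117.

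**Figure D3:**
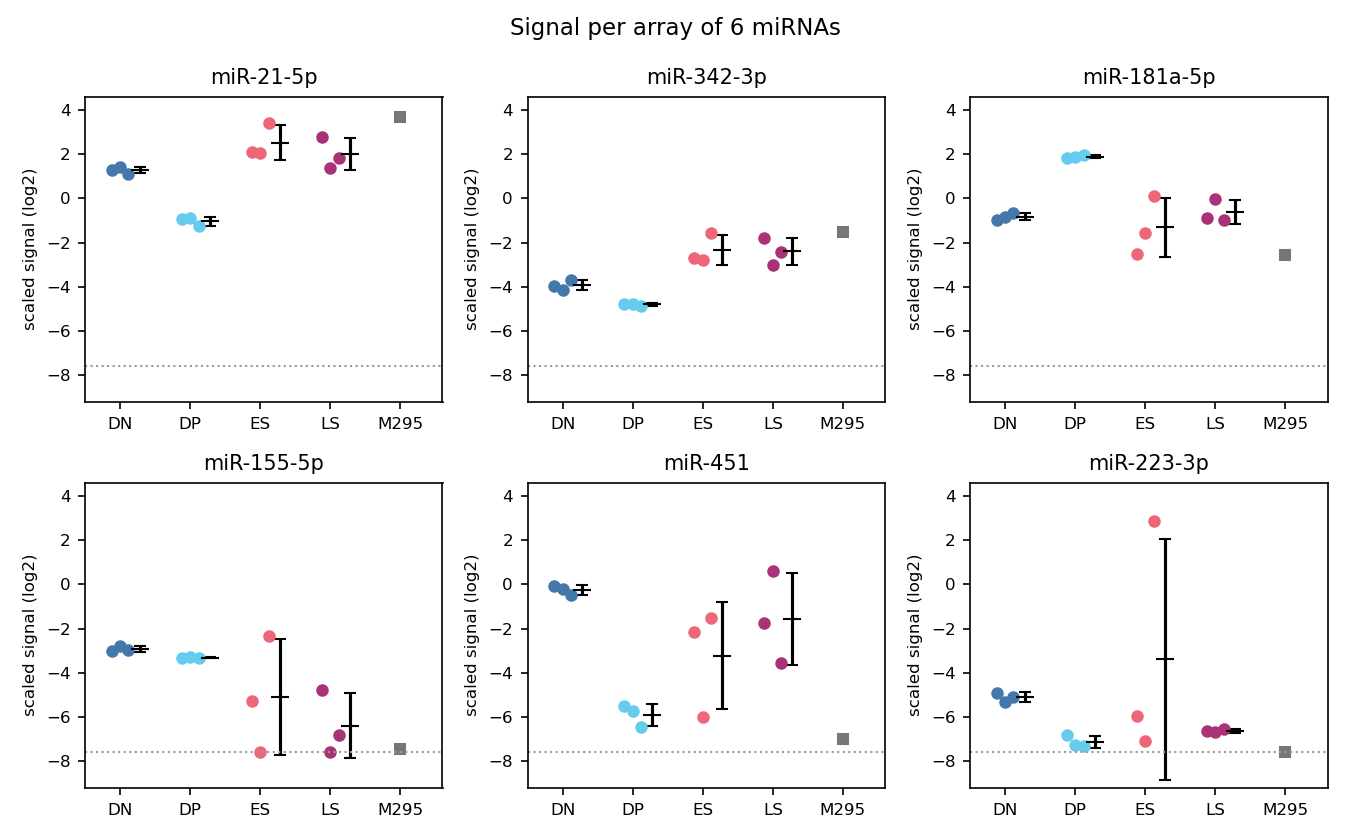
Points give the scaled log2 signal of 6 miRNAs on each array, with the mean and SD of each group of 3 as horizontal and vertical bars beside the points, M295 as a square, and the floor of -7.59 as a dotted line. miR-21-5p is higher on every T-ALL array than on every DP array, miR-181a-5p is lower, and miR-223-3p reaches 2.85 on ES 3 alone.

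Markers of other cell types were followed on each array, since a sorted population can hold other cells. Of 3 erythroid markers on the array 2 were above background on some primary array, miR-451 at log2 signals of -0.06, -0.22 and -0.50 on the DN arrays, -2.17, -5.98 and -1.53 on the ES arrays and -1.76, 0.58 and -3.56 on the LS arrays. Of 3 myeloid markers 1 was, miR-223-3p, which was at 2.85 on ES 3 and between -7.08 and -5.93 on the other 5 T-ALL arrays. It was also above background on the 3 DN arrays (-4.89, -5.31 and -5.08) and on no DP array (-7.31 to -6.79). All 4 mature lymphocyte markers were above background on some array, and miR-342-3p was on all 12. Of 8 endothelial and stromal markers 1 was above background (miR-126-3p, on the 3 DN arrays), of 7 epithelial markers 3 were, and of 6 tissue-restricted controls 2 were. The epithelial markers were above background on T-ALL arrays alone among the primary ones: miR-141-3p on 4 (-6.18 to -5.94), miR-200c-3p on 3 (-6.49 to -6.25) and miR-200b-3p on LS 3 (-5.91), against at most -7.20, -7.59 and -7.50 on the thymocyte arrays. The 2 controls were miR-9-5p on some T-ALL arrays and miR-206-3p, a muscle miRNA, on the 3 DP arrays. Of the remaining lists, the Dlk1-Dio3 cluster had 0 of 14 members tested, the clusters of miR-99 or miR-100 with let-7 and miR-125 1 of 7, miR-21 1 of 2 and the miR-34 family 2 of 4, of which miR-449a-5p rose and miR-34a-5p fell in T-ALL (log2 fold change -1.60, SE 0.53), the latter call ending without any 1 of 7 arrays (adjusted p up to 0.0597).

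The line M295 was set beside the 6 primary T-ALL arrays without a test, since it has 1 array. Of 110 miRNAs above background on M295 and on all 6 T-ALL arrays, 16 were above the range of the T-ALL arrays, 41 below it and 53 within it. By chance, an array like these 6 would be above their range for 14.3% of miRNAs and below it for 14.3%. The 16 above are thus close to that share, and the 41 below exceed it. In the wider set of 258 miRNAs 98 were above the range and 50 below, but 257 of these are above background on M295 and 47 on no T-ALL array, so that set favours miRNAs high in M295. The 8 furthest above were miR-210-3p, which is induced by low oxygen (log2 signal -0.53 against at most -4.54), miR-672-5p (-2.38), miR-468-3p (-1.53), miR-669e-5p (-2.70), and 4 miRNAs above background on no T-ALL array. These 4 were miR-466j (at least 15.8-fold above the T-ALL mean), miR-206-3p (at least 8.39-fold), miR-669f-5p (at least 9.08-fold) and miR-669o-5p (at least 14.6-fold). The 8 furthest below were miR-128-3p (-2.57 against at least -1.07), miR-467f (-6.30), miR-706 (at the floor of -7.59), miR-451 (not above background on M295, at least 24.2-fold below the T-ALL mean), miR-1949 (-1.22), miR-714 (-4.45), miR-15b-5p (0.88) and miR-181a-1-3p (-5.66).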

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

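The test of other white blood cells on ES 3, the 3 tests on features high in DP, and, for the array names without a gene, those of background and of scaling on an unchanged background were chosen only after the result was seen. The Fisher test of these names was not planned either, since their split from the others was added after the data were seen. All other tests here were set before their values were seen, though the names without a gene and miR-223-3p on ES 3 are patterns noticed in these data.

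On the 6 T-ALL arrays 53 miRNAs were examined for an array far from the others, and 4 had such an array, where chance gives about 1 in 20. These were miR-181d-5p on ES 3 (log2 signal -4.27), miR-29a-3p on ES 3 (0.39), miR-29b-3p on ES 3 (-0.65) and miR-30e-3p on ES 1 (-5.87). The number of miRNAs above background was far from the others on ES 1, at 115. Of 179 miRNAs above background on ES 2 and ES 3, 68 were not above background on ES 1.

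Late-stage and early-stage T-ALL, each against DP, differed by a test of the difference in miR-712-5p (log2 difference 1.45), miR-3473b (1.33), miR-344i (1.32), miR-3473 (1.16), miR-690 (0.96) and miR-3968 (-0.86). The DP arrays cancel in this difference, so these are the 6 calls of LS against ES and no further result. Among the viral miRNAs on the array, which no comparison uses, mcmv-miR-M23-1-3p was above background on 1 T-ALL array, mcmv-miR-M87-1 on 3 and mghv-miR-M1-2-3p on 3, and none of these on a thymocyte array. However, mcmv-miR-M23-1-5p and mcmv-miR-m88-1 were above background on all 6 T-ALL arrays, all 6 thymocyte arrays and M295. Signal on viral features is thus not particular to T-ALL.

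Of the 14 tested array names that matched no miRNA gene of the reference gene table, 9 rose and 1 fell in T-ALL against thymocytes, against 63 rises and 58 falls among the other 215 (Fisher exact test, two-sided, p = 0.0136, adjusted over 7 comparisons p = 0.0191). Among the 9 rises is miR-3102-5p.2-5p (log2 fold change 1.82), a form of name that the matching did not read. Since miR-3102-5p did match a gene, 1 of the 14 is misplaced, and the test was not repeated without it. A difference between the slides is argued against, since the median of the 14 names exceeded that of the others by 1.52 within slide 2 and 1.61 within slide 1. Scaling was first tested by quantile normalization and RMA-like processing together, which left it open, since the excess of 1.51 was 1.37 with the first and 0.48 with the second. RMA-like processing also changes the background, and scaling on an unchanged background is argued against: the excess of these names over the others in the medians of each array, 1.36 (SE 0.29), was 1.32 (SE 0.29) with quantile normalization and 1.20 (SE 0.27) with the deposited values. A factor per array cancels in this excess, which was 1.36 also with the 75th percentile over all miRNAs. The deposited values appear quantile normalized too, so the 2 settings are not separate checks. Background of the arrays stays open, since the excess of the median fold changes was 0.48 with RMA-like processing and 0.52 with normexp background, whose shared offset draws dim signals towards 0. In the medians of each array more of the excess of 1.36 stayed, 0.99 (SE 0.21) with RMA-like processing and 1.00 (SE 0.25) with normexp background, so the measures differ. An origin shared by these RNAs, which could vary between RNA preparations, stays open too, since their mean correlation between arrays of a group was 0.11, at the 66.5th percentile of random sets. T-ALL and thymocytes also differ in tissue, so a biological difference between leukaemia and thymus cannot be told apart from spleen against thymus.

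The signal of miR-223-3p, a miRNA of myeloid cells, was 2.85 on ES 3 and at most -5.93 on the other T-ALL arrays. Faulty spots or 1 faulty probe are argued against, since both probes, with 20 spots each, exceeded the highest other T-ALL array by at least 8.58. Other white blood cells in the sort may be a source, although the sort for CD4 and CD8 would remove them, and mature lymphocyte markers, of which miR-342-3p is above background on all 12 primary arrays and miR-146a-5p is also an activation miRNA, exceeded the highest other T-ALL array by a median of 0.93 (miR-150-5p by 1.62, miR-146a-5p by 2.98 and miR-342-3p by 0.24, while miR-342-5p, at the floor, was at -0.21). Few markers of other white blood cells are on the array. Of the 3 myeloid markers, miR-223-5p is by name the other arm of miR-223, and miR-143-3p is also in the endothelial and stromal list. Neither was above background on any array, which says little about myeloid cells. Lymphocyte markers cannot show myeloid cells, so other white blood cells as a source stay open. Neither a mislabelled sample nor a difference between leukaemias was tested.

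Against DN, ES and LS alike, DP had high signals for a set of features: 15 mouse features were above background on every DP array and on no other primary array, 5 of them from the Sfmbt2 cluster. Of the viral features, 2 had the same pattern, and all of these 15 and 2 features were above background on M295. Another RNA that binds the probes of many features stays open: the viral features had a DP excess of at least 2.18, but they were chosen for their signal on DP, so this excess decides nothing. Scaling of the arrays on an unchanged background is argued against for the Sfmbt2 members in DN, 5 of which are among the 15 features. With the 75th percentile over all miRNAs, quantile normalization and the deposited values, the medians of the 15 features lay between 1.17 (SE 0.10) and 2.08 (SE 0.15) below DP in DN, ES and LS. These features too were chosen for their signal on DP alone, so their differences decide nothing about scaling. With the same scalings, in the same order, the medians of the 27 Sfmbt2 members in DN were at -0.71 (SE 0.08), -0.95 (SE 0.06) and -0.71 (SE 0.05) from DP, with 12 called as lower each time. In ES and LS the members varied too much between arrays for this test (LS -0.96, SE 0.51, as reported). Background of the arrays stays open, since the median log2 fold change of the Sfmbt2 members in DN against DP, -0.998 as reported, was 0.037 with normexp background and -0.17 with RMA-like processing. In the medians of each array the difference from DP was -0.14 (SE 0.08) with normexp background and -0.40 (SE 0.02) with RMA-like processing. Both draw dim signals towards 0 by construction, and 6 and 11 members were called as lower there. A higher level of these miRNAs in DP cells, a difference that the groups name, is untested against that.

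Other splits of the arrays were fitted to see whether chance can be excluded. For T-ALL against thymocytes, in a fit of 2 groups, the real split gave 82 miRNAs, and among 100 splits, the real one included, 1 gave as many, with 47 as the highest other. Splits of single arrays mostly mix DN, DP, ES and LS arrays on both sides, which widens the spread within each side. The share therefore speaks against a random division of single arrays and does not exclude chance between whole groups. With 3 arrays against 3 the 10 splits are too few for a share under 0.05: the real split and the highest other gave 106 and 0 (ES against DP), 134 and 0 (LS against DP), 67 and 0 (DN against DP), 15 and 0 (ES against DN) and 76 and 0 (LS against DN). For each of these 5 comparisons 1 of 10 splits gave as many. For LS against ES the real split gave 6 and the highest other 60 (ES 1, ES 2 and LS 3 against ES 3, LS 1 and LS 2), and 3 of 10 gave as many, which points to a structure of these arrays other than stage. Between LS and ES 3 miRNAs were called with slide as a block.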

How the results depend on the processing

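The restriction to miRNAs with a gene in the reference table, the list tests without ES 1 or ES 3, the replicate block for DP and LS alone and the M295 set above background on all 7 arrays were chosen only after the data were seen. Of 12247 recomputed named values, 11050 kept their side of the threshold, 687 lost their call, 484 gained one and 26 reversed. Uncalled sign changes were not counted, and causes not tested unless a construction is given.

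The reported counts were 131 for T-ALL against thymocytes, 106 for ES against DP, 134 for LS against DP, 6 for LS against ES, 67 for DN against DP, 15 for ES against DN and 76 for LS against DN, and moved by over 1.5 times as follows. Restricting to miRNAs above background on all arrays, which tests fewer miRNAs, gave 60 for T-ALL against thymocytes, 60 for ES against DP, 68 for LS against DP, 33 for DN against DP, 7 for ES against DN and 35 for LS against DN. Within slide 1, with fewer arrays, the counts were 30, 29, 56, 18, 3 and 3 in the same order, and 0 for LS against ES, and within slide 2 they were 165 for ES against DP, 114 for LS against ES, 123 for DN against DP, 137 for ES against DN and 118 for LS against DN. A log2 fold change of at least 1 left 83 for T-ALL against thymocytes. With only the groups compared in the fit, ES against DP had 62, LS against ES 0 (14 at an unadjusted p under 0.05 in limma), DN against DP 164 and ES against DN 3. Array weights, whose estimation did not fully converge, gave 31 for LS against ES, 157 for DN against DP and 135 for LS against DN. Normexp background gave 43 for DN against DP, 0 for ES against DN (39 unadjusted) and 46 for LS against DN. For LS against ES, quantile normalization gave 2, no filter on dim miRNAs 0 (42 unadjusted), the slide block 3, the replicate block 3 and the restriction to miRNAs with a gene in the reference gene list 3. For ES against DN, the 75th percentile over all miRNAs gave 42, quantile normalization 27, the brightest probe 9, no filter 1, the slide block 9 and the replicate block 6, and no filter gave 21 for LS against DN.

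The replicate numbers are not shown to pair the arrays of any groups, and 5 of the 12 arrays correlated best with their own number. With the replicate number as a block in all groups, the counts were 84 for ES against DP, 135 for LS against DP, 61 for DN against DP and 66 for LS against DN. That block ended the list calls of miR-15/16 in ES against DP (adjusted p = 0.0650) and miR-181 in ES against DN (0.0529). The replicate block for DP and LS alone gave 124 for LS against DP and ended the named calls of let-7a-5p, miR-155-5p, miR-29b-3p and miR-30a-5p and the list calls of miR-15/16, miR-30 and miR-181, and no other named call or list call there.

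Leaving out 1 array gave 110 to 154 calls for T-ALL against thymocytes, 69 to 120 for ES against DP, 99 to 164 for LS against DP, 1 to 55 for LS against ES, 44 to 101 for DN against DP, 0 to 40 for ES against DN and 32 to 117 for LS against DN. The excess of miRNAs above background in T-ALL ranged from -2.93 without ES 3 to 22.9 without ES 1.

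Within slide 2, 23 values reversed. They were miR-146b-5p in T-ALL against thymocytes (0.89); in LS against ES miR-144-3p (-3.00), miR-181a-5p (-1.10), miR-18b-5p (1.61), miR-195-5p (-0.83), miR-20b-5p (1.16), miR-26a-5p (-0.80), miR-30a-5p (-0.72) and miR-451 (-2.03); in ES against DP miR-155-5p (0.96), miR-20a-5p (-0.85), miR-210-3p (1.36), miR-23a-3p (0.72) and miR-322-5p (1.60); in LS against DP miR-126-3p (0.68); and in ES against DN let-7c-5p (-0.57), miR-146b-5p (2.59), miR-181a-5p (0.86), miR-23a-3p (0.58), miR-29a-3p (1.05), miR-31-5p (1.54), miR-322-5p (1.27) and miR-34a-5p (0.77). The others were let-7a-5p in ES against DP with the 75th percentile over all miRNAs (0.049), miR-223-3p in ES against DN without ES 3 (-1.41, and up to 3.56 without ES 2) and miR-466f-3p in LS against DN with normexp background (-0.079).

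Scaling moved the median log2 fold change of all miRNAs by over 0.1 in some comparisons. With the 75th percentile over all miRNAs it went from 0.07 to 0.59 in ES against DP, from 0.19 to 0.03 in LS against DP, from 0.28 to -0.38 in LS against ES, from 0.15 to 0.45 in DN against DP, from -0.04 to 0.13 in ES against DN and from 0.16 to -0.31 in LS against DN. With quantile normalization it was -0.26 in T-ALL against thymocytes, -0.11 in LS against DP, 0.06 in LS against ES and -0.18 in LS against DN. With normexp background it was -0.01 in T-ALL against thymocytes, 0.20 in ES against DP, -0.0038 in LS against ES and -0.09 in LS against DN. Other shifts were to -0.06 in LS against DP, 0.03 in LS against ES and -0.03 in LS against DN with RMA-like processing, and to -0.06, 0.05 and -0.08 in these and -0.14 in ES against DN with the deposited value table.

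The balance of higher and lower calls moved by over 10 points with some scalings. With the 75th percentile over all miRNAs it was 83 higher and 34 lower in ES against DP (48 and 58 as reported), 0 and 9 in LS against ES (5 and 1), 29 and 29 in DN against DP (24 and 43), 40 and 2 in ES against DN (9 and 6) and 43 and 34 in LS against DN (59 and 17). Quantile normalization gave 63 and 80 in LS against DP (74 and 60), 2 and 0 in LS against ES, 19 and 8 in ES against DN and 47 and 36 in LS against DN. RMA-like processing gave 56 and 83 in T-ALL against thymocytes (72 and 59), 52 and 78 in LS against DP, 4 and 0 in LS against ES, 7 and 9 in ES against DN and 36 and 40 in LS against DN, and the deposited values gave 61 and 75 in LS against DP and 46 and 30 in LS against DN.

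For M295, 81 miRNAs were above the T-ALL range and 72 below with quantile normalization, 85 and 73 with RMA-like processing and 81 and 73 with the deposited values, against 98 and 50 as reported. Among the 110 above background on all 7 arrays these were 12 and 45, 13 and 51, and 12 and 45, against 16 and 41.

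The calls of the miR-181, miR-30 and Sfmbt2 lists in T-ALL against thymocytes ended with quantile normalization (adjusted p = 0.117, 0.0777 and 0.0928) and with RMA-like processing (0.0664, 0.0575 and 0.0664). Signal over background limits dim miRNAs most: 108 of the 229 tested were above background on all 12 primary arrays.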

Other observations

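All values here were picked out after the data were seen.

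In DN against DP, thymocytes also differed in miR-449a-5p, which was 4.35-fold lower in DN (log2 fold change -2.12, SE 0.64, n = 3 each, adjusted p = 0.0299), a call that ended without any 1 of the DN and DP arrays (adjusted p up to 0.0877). In LS against DP, 2 members of the miR-232724 clusters, miR-23a-3p (-1.57, and -0.87 without LS 1) and miR-27a-3p (-1.54, and -0.82 without LS 1), were lower, while miR-27b-3p (1.21), from the other copy of the cluster, was higher. These calls ended without DN 1, any DP array or LS 1 for the first 2 miRNAs (adjusted p up to 0.121) and with slide as a block (0.0553 and 0.0602), and without DP 3 or LS 2 for miR-27b-3p (adjusted p up to 0.0694).

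miR-9-5p, a miRNA of brain, was above background on ES 1 (log2 signal -3.76), ES 3 (-5.18), LS 1 (-2.69) and M295 (-1.69) and on no thymocyte array.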
